A study of Mus musculus with 2 samples.

How the data were processed

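H3K27ac was measured by chromatin immunoprecipitation and sequencing in 2 biological replicates of embryonic day 13.5 mouse hindbrain, each a pool of male and female embryos, with library fragments of 300 to 500 bp per the labels. The replicates were separate tissue samples numbered by the labels and form 1 group, so no comparison of conditions and no test with the replicate as the unit could be made. The replicates are therefore compared with each other, and every other result is a description of the replicated list, with values of each replicate's own list printed for the leading items and wherever they change a call.

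The authors deposited 4 peak lists in narrowPeak format on the mm10 build. Per the file descriptions deposited with them, each replicate's list was called on that replicate's alignments against its own control library, a different one for each replicate, the pooled list was called on both replicates with both controls, and the replicated list was made from the other 3. The fold enrichment of a peak is the authors' ratio of immunoprecipitated over control signal, per the deposited format, and was not scaled between lists. The −log10 p and −log10 q of each peak are likewise values of the authors' peak caller, per the deposited format. The caller, its version, its threshold and the overlap rule behind the replicated list are not stated in the deposited files or labels. The lowest −log10 q in the files was 0.629 in the replicated list, 0.618 in the pooled list, 0.517 in replicate 1 and 0.446 in replicate 2. The read counts and the sequencing depth are unknown, since the files hold peaks alone, and no limit of detection that needs them is given. A missing peak means that the caller listed none there.

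Peaks on the assembled chromosomes 1 to 19, X and Y were used, which left out 9 scaffold peaks of the replicated list, 12 of the pooled list and 11 of each replicate list. Gene positions came from GENCODE mouse release M21, and sequence from GRCm38 patch 6, the assembly behind mm10. Coordinates are given 1-based. Peaks were shared where their overlap covered at least 50% of either peak, computed with own code checked against bedtools 2.31.1, and the chance level came from 100 seeded circular shifts of one list along each chromosome. Summits were assigned in the order promoter (within 1 kb of a TSS of any gene type), exon, intron and intergenic. A gene had a promoter peak where a peak overlapped the 1 kb either side of any of its TSSs, and its promoter fold is the highest fold among those peaks. Breadth is the length covered by peaks within 10 kb of the most upstream TSS. Distal peaks are those whose whole interval lies more than 2.5 kb from every TSS. Percentages have exact Clopper-Pearson 95% intervals, which cover counting error over peaks or genes only.

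The 22 gene lists, the 14 motifs, the tests, the other settings to be tried and the rule for naming genes were fixed before the data were examined. Promoter peaks of a list were compared with those of all other protein-coding genes, 21938 in all and receptor genes included, by a two-sided Fisher's exact test. Breadth was compared by a two-sided permutation test with 100000 random lists of the same size. Both were adjusted by the Benjamini-Hochberg method over the 22 lists, with a threshold of 0.05. Hox paralog groups 1 to 5 and 9 to 13 were compared by a two-sided Fisher's exact test. For motifs, the central 500 bp of each distal peak was searched on both strands, and each window was paired with a random window outside peaks on the same chromosome and in the same bin of GC content, 2 percentage points wide, with up to 200 draws each; 93.8% of peak windows found a partner and the others were left out. Control windows were not matched on repeat content. The ratio of the shares of windows with a match has a 95% interval from 1000 bootstrap samples of chromosomes. Regions were built by merging neighbouring peaks across gaps of a fixed length and ranked by covered bases. Computations used python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.

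Genes were named by a fixed rule: every Hox gene; in each other list the 3 members of highest promoter fold, up to 3 unmarked members in alphabetical order, and any member on a side of 5 or fewer; the 10 promoters of highest fold marked in both replicates; the 10 distal peaks of highest fold; the 20 longest merged regions and list genes among the 100 longest; and the 5 strongest peaks of each replicate list without any overlap in the other. Examples of broad coverage within lists, X-linked genes, genes marked in 1 replicate alone and the widest peak fall outside this rule and were chosen after their values were seen.

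The code was tested on simulated data and on parts of the real lists. Of the 135068 peaks of replicate 1, 40.1% were copied with a small shift into a second list, and 40.5% were recovered as shared. Shared peaks in the real lists differed from those of bedtools at 0 peaks. Of 200 random gene lists, 4% had a Fisher p under 0.05, and of 100 random lists 2% had a permutation p under 0.05 for breadth, while all 50 planted lists passed in each test. Promoter calls and TSS distances of 300 peaks drawn from the replicated list, and covered lengths of 200 genes, matched direct calculations. The exon, intron and intergenic classes were not checked in this way. A motif planted in 30.9% of 641 windows was recovered in 30.7% above controls, and a motif not planted had a ratio of 1.19 in those 641 windows.

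Other settings changed 1 choice at a time: the overlap that counts as shared (1 bp, or 50% of both peaks), a stricter threshold of −log10 q of at least 2, equal numbers of top peaks, promoter windows of 500 bp and 2.5 kb, TSSs of protein-coding genes only, a breadth window of 25 kb, other backgrounds, distal distances of 1 and 10 kb, a merging distance of 5 kb, distal peaks only, whole peaks or unmatched windows for motifs, the pooled list, and each replicate's own list, which leaves out the other replicate. Restricting the replicated list to peaks found in both replicate lists, and drawing the motif control windows again with another seed, were added after seeing the data.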

Results

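Histone H3 acetylated at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in the hindbrain of healthy mouse embryos of strain B6NCrl at embryonic day 13.5. At this stage the hindbrain is forming the cerebellum, the pons and the medulla. Each sample was a pool of male and female embryos. There was 1 group of 2 biological replicates and no second condition. The measurements were 4 peak lists on the mm10 build: 1 for each replicate, 1 for both replicates pooled, and 1 of replicated peaks. Per the file descriptions, the replicated list was made from the other 3. On the assembled chromosomes, replicate 1 had 135068 peaks, replicate 2 had 116814, the pooled list had 155470 and the replicated list had 75519. The files hold peaks and no read counts, so the sequencing depth of each library is unknown. Fold enrichment is the authors' ratio of immunoprecipitated over control signal at a peak. The replicates had different control libraries and the lists share no scale, so folds are ranked within a list and the replicate values stand side by side. Peaks and genes are not independent replicates, so every p-value below describes these peak lists and does not extend to other embryos.

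The comparison of the replicates with each other asked how much of the acetylation landscape was seen in both pools of embryos. The strong peaks were shared: all of the 10000 peaks of highest fold in each replicate had a counterpart in the other list. Among these were the promoters of Actb, the cytoskeletal actin used as a housekeeping gene, with a fold of 62.5 in replicate 1 and 57.8 in replicate 2, of Msi1, an RNA-binding protein of neural progenitors, with 53.2 and 47.0, and of Hoxa2, which patterns the rhombomeres, with 53.7 and 46.2. Weak peaks were shared far less often. Of all replicate 1 peaks, 46.5% overlapped a replicate 2 peak by at least 50% of either peak (exact binomial 95% interval 46.3 to 46.8), and of replicate 2 peaks 58.9% overlapped a replicate 1 peak (58.6 to 59.2). Circular shifts of one list along the chromosomes gave means of 3.20% and 3.75%. The shared part rose with fold, from 20.1% in the lowest quintile of replicate 1 to 96.6% in the highest, and from 34.2% to 98.6% in replicate 2. Shared peaks had a median fold of 4.66 in replicate 1 and 4.38 in replicate 2, against 3.14 and 3.30 for the others. Over 72283 pairs of shared peaks, Pearson's r of the log2 folds was 0.74 and Spearman's rho was 0.604, both across peaks within a pair of lists.

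**Figure D1:**
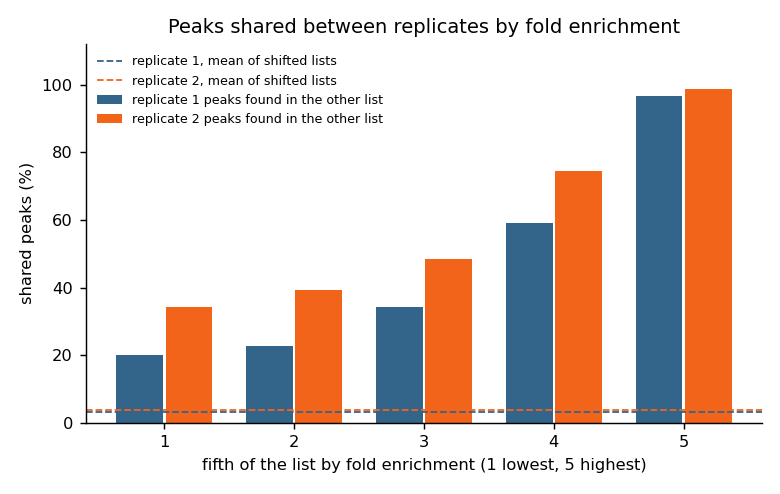
Percentage of peaks found in the other replicate's list (vertical axis) for each quintile of the peaks of replicate 1 and replicate 2 ordered by fold enrichment (horizontal axis, lowest to highest). Bars are the observed percentages and dashed lines the means of 100 circular shifts; the lowest quintiles stand at 20.1% and 34.2% and the highest at 96.6% and 98.6%.

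Peaks with no overlap of even 1 bp in the other list numbered 64045 in replicate 1 (47.4% of the list) and 39832 in replicate 2 (34.1%). The strongest of them were modest. In replicate 1 they lay near Aco1 (chromosome 4, 40014749 to 40015120) and in an intron of Tbca, each with a fold of 8.22, and in introns of Tox, Arhgap24 and Pbx3, each with a fold of 7.95. In replicate 2 they lay in an intron of Pknox1, a homeodomain partner of Hox proteins (chromosome 17, 31580026 to 31580453, fold 8.01), near Prex1 (7.46), Stmn2 (7.18) and Slc44a1 (6.89), and in an intron of Tshz3 (6.89). The strongest of them ranked 13116 in replicate 1 and 12621 in replicate 2. Requiring 50% of both peaks lowered the shared part of replicate 2 to 36.4%.

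The replicated list asked which pooled peaks stood up across replicates. Every replicated peak was a pooled peak with the same coordinates and fold, and the replicated list held 48.6% of the pooled peaks (exact binomial 95% interval 48.3 to 48.8) and 77.7% of their covered bases. The broad domains of the hindbrain Hox genes were kept, the widest being the 56097-bp peak over Hoxb3, Hoxb4, Hoxb5 and Hoxb6. The peaks left out were small and weak, with a median width of 217 bp and a median fold of 2.73, against 600 bp and 4.19 for those kept. Of the replicated peaks, 61266 (81.1%) overlapped peaks of both replicate lists by 50% of either peak and 14253 (18.9%) did not. Of the latter, 9001 had such an overlap in replicate 1 alone, 4711 in replicate 2 alone and 541 in neither, with a median fold of 3.30 against 4.62. No pooled peak that met the rule in both replicate lists was missing from the replicated list. However, 13894 replicated peaks lacked even 1 bp of overlap in 1 or both replicate lists. Overlap with both deposited replicate lists alone therefore cannot have given the replicated list, and how these peaks entered it is not stated.

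The next comparison asked where in the genome the mark lay. The highest fold of the list lay at the promoter of Arrdc3, an arrestin-related gene, with 80.9 (chromosome 13, 80882314 to 80887180; 68.8 in replicate 1 and 71.6 in replicate 2). It was followed by the histone methyltransferase gene Kmt5b at 78.8, by the promoter shared by Gm10762 and Zc3h6 and that of the transcription factor gene Klf7, both at 78.6, and by the transcription factor gene Sp3 at 77.95. Zfp532 had 74.98, Zc3h4 had 73.7 and the peak shared by Rhof and the histone methyltransferase gene Setd1b had 73.3. In all, 12541 of 21938 protein-coding genes (57.2%, exact binomial 95% interval 56.5 to 57.8) had a replicated peak within 1 kb of a transcription start site (TSS), and 12278 of them also had one in both replicate lists. The list of replicate 1 gave 13162 genes and that of replicate 2 gave 12733. By summit, 25.2% of replicated peaks lay in promoters, 4.06 times the mean of 100 circular shifts. Exons held 4.15% (1.25 times), introns 47.2% (1.198 times) and intergenic sequence 23.5% (0.460 times), each outside the range of the shifts.

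Gene lists fixed in advance asked which cell classes and positions carried the mark at their promoters. Hindbrain and isthmus patterning regulators, neural progenitor genes and neuronal genes were marked more often than other genes, while forebrain regulators and genes of other organs were rarely marked. The test counts marked promoters and does not ask whether a gene is particular to the hindbrain. Of the hindbrain and isthmus patterning regulators, 18 of 21 had a replicated promoter peak (exact adjusted p = 0.0137). The highest folds were those of Meis1, a cofactor of Hox proteins (56.3; 50.7 in replicate 1 and 46.2 in replicate 2), and of the nuclear receptor genes Nr2f2 (45.7; 42.2 and 38.4) and Nr2f1 (45.4; 39.6 and 40.9). Egr2, Fgf8 and Wnt1, which act earlier in rhombomeres 3 and 5 or at the isthmus, had no replicated peak, but Egr2 had one of fold 3.29 in replicate 1 alone and Wnt1 one of 3.56 in replicate 2 alone. All 21 neural progenitor and radial glia genes were marked (exact adjusted p = 8.41e-05), led by Msi1 (61.8), the cadherin gene Cdh2 (55.7) and Nfib (44.9). All 19 pan-neuronal genes were marked (exact adjusted p = 1.05e-04), led by the tubulin gene Tubb3 (40.1), Rbfox3, which encodes NeuN (39.0), and the tau gene Mapt (37.5). All tests of lists were two-sided Fisher's exact tests against every other protein-coding gene, 57.2% of which were marked, with Benjamini-Hochberg adjustment over 22 lists.

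Lists that hold the cerebellar lineages were also marked more often than other genes. The median fold of marked members was 16.7 in the GABAergic list and 10.9 in the rhombic lip list, against 13.7 over all marked genes. Of 22 genes of the cerebellar and brainstem GABAergic lineage, 19 had a promoter peak (exact adjusted p = 0.0115), with the highest folds at Gad2, which encodes an enzyme of GABA synthesis (31.5), Rora (30.2) and Lhx5 (28.7). Ptf1a, the regulator that starts this lineage, Prdm13 and Tal2 had no replicated peak, and Ptf1a and Prdm13 had a weak peak in replicate 1 alone (3.56 and 3.02). Of 20 genes of the rhombic lip and cerebellar glutamatergic lineage, 17 were marked (exact adjusted p = 0.0188), led by Nhlh2 (47.1), Mab21l1 (33.2) and the promoter shared by Zic1 and Zic4 (30.2). Atoh1, the rhombic lip regulator, had a peak of fold 2.85 in replicate 1 alone, and Eomes and Tbr1 had none in any replicate. Beyond these lineages, 13 of 14 genes of the sonic hedgehog pathway and ventral midline were marked (exact adjusted p = 0.0127). Ptch1, the receptor, had 40.3, Mycn 34.7 and Cdon 30.9, and only Hhip was unmarked. All 14 housekeeping genes were marked (exact adjusted p = 0.00168), with Actb at 70.5, Ywhaz at 65.7 and Eef1a1 at 49.7. The rhombic lip list missed the threshold with only peaks found in both replicate lists (exact adjusted p = 0.0529) and with olfactory and vomeronasal receptors taken out of the background (0.0591), in a range of 0.00880 to 0.0591 over the alternatives.

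Lists of other regions and organs lay below other genes. Of 21 forebrain regulators, 2 were marked (exact adjusted p = 5.43e-05): Satb2 with a fold of 7.27 and Dlx2 with 3.30, Dlx2 in replicate 1 but not in replicate 2. Arx, Dlx1 and Dlx5 were among the 19 with no replicated peak. Replicate 1 had 4 of the 21 marked, with Dlx6 and Otx1 besides Satb2 and Dlx2, and replicate 2 had 3, with Gsx2 and Otx1 besides Satb2, and the list stayed below other genes (largest exact adjusted p = 7.75e-04 over the alternatives). None of 14 erythroid genes had a replicated promoter peak (exact adjusted p = 5.43e-05); Klf1, Nfe2 and Slc4a1 had one in replicate 1 alone. The adult and embryonic haemoglobin genes, Alas2 and Gata1 had none, and reads can be shared between near-identical haemoglobin copies, so that absence is uncertain. Of 12 liver genes, 2 were marked (exact adjusted p = 0.0127), Afp at 8.42 and Apoa1, without a peak in replicate 1, at 3.08, while Ahsg, Alb and Apob were not. Of 14 heart and skeletal muscle genes, 2 were marked (exact adjusted p = 0.00458), the natriuretic peptide gene Nppa at 7.63 and Myl2 at 4.31. Of 14 microglia and macrophage genes, 3 were marked (exact adjusted p = 0.0188), namely C1qb (4.44), Csf1r (4.29) and Cd68 (3.798), and the list of replicate 2 had 5. Csf1r had no promoter peak in replicate 2. Of 1464 olfactory and vomeronasal receptors, 2 were marked, Vmn1r4 at 17.8 and Olfr94 at 6.62. The heart and muscle call ended with a promoter window of 2.5 kb (exact adjusted p = 0.324, range over the alternatives 0.00151 to 0.324), and the microglia call ended in the pooled list (0.228) and in the list of replicate 2 (0.139, range 0.00406 to 0.228).

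The remaining lists of cell classes did not pass the threshold. Among brainstem motor, serotonergic and noradrenergic genes, 7 of 18 were marked (exact adjusted p = 0.186), led by Lmx1b (13.3), Ddc (11.2) and Phox2b (9.08), and Dbh, Fev and Mnx1 had no replicated peak. Among oligodendrocyte and astrocyte genes, 6 of 15 were marked (exact adjusted p = 0.219), with Sox10 at 6.08, Cnp at 5.95 and Pdgfra at 4.56, and Aldh1l1, Cspg4 and Gpr17 without. Among cell cycle genes, 10 of 13 were marked (exact adjusted p = 0.1996), with Aurka at 10.1, Mcm5 at 9.71 and Mcm2 at 7.98, and Ccnb1, Ccnb2 and Mki67 without. Endothelial and pericyte genes had 7 of 15 marked (exact adjusted p = 0.464), with Pdgfrb at 6.16, Cldn5 at 5.28 and Kdr at 5.19. The list of replicate 1 and the pooled list each had 10 of the 15 marked, a larger share than in all genes (exact adjusted p = 0.811 and 0.848, range over the alternatives 0.323 to 1.00), as did a 2.5-kb window (60%). Genes of meninges and mesenchyme had 4 of 12 (exact adjusted p = 0.186), namely Foxc1 (9.08), Foxc2 (4.46), Tbx18 (3.96) and Twist1 (2.97). Twist1 had no promoter peak in replicate 2. The list of replicate 1 had 8 of the 12 marked and the pooled list had 9, a larger share than in all genes (exact adjusted p = 0.811 and 0.477, range over the alternatives 0.0529 to 0.811). Choroid plexus genes had 6 of 10 (exact adjusted p = 1.00), with Foxj1 at 9.25, Otx2 at 4.46 and Clic6 at 4.13, and Aqp1, Cldn2, Kcnj13 and Kl without. Choroid plexus genes were marked at 7 of 10 promoters in replicate 1 and at 2 of 10 in replicate 2, where the list lay below other genes (exact adjusted p = 0.0362, range over the alternatives 0.0362 to 1.00). The motor, serotonergic and noradrenergic list lay below other genes with a 500-bp window (exact adjusted p = 0.0248) and with only peaks found in both replicate lists (0.0433). It had 12 of 18 marked, a larger share than in all genes, in the pooled list (exact adjusted p = 0.848, range 0.0248 to 0.848) and in the list of replicate 2 (0.634). The cell cycle list lay above other genes in the pooled list (exact adjusted p = 0.0343, range 0.0343 to 0.604).

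**Figure D2:**
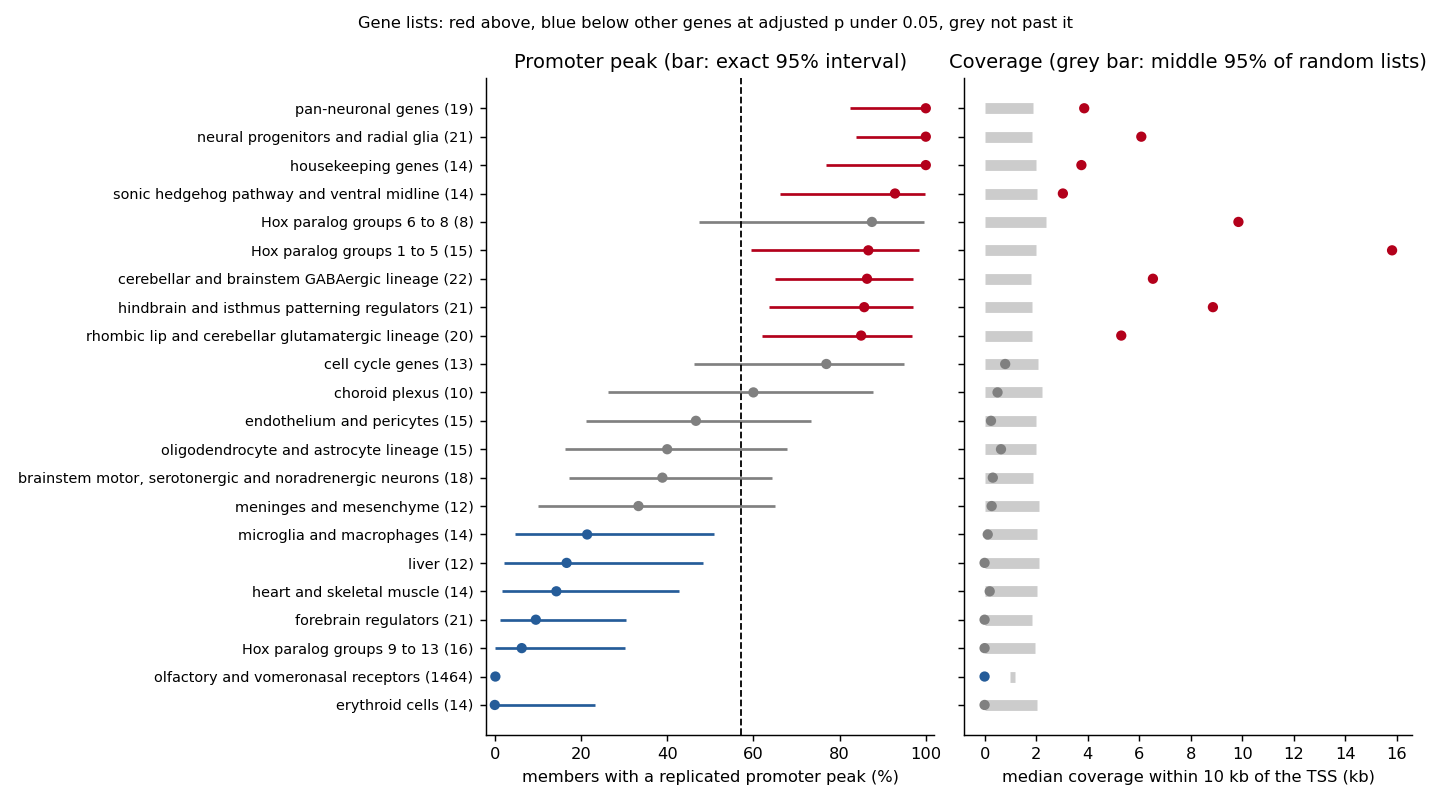
Left, percentage of each list's members with a replicated promoter peak (points) with exact 95% binomial intervals (lines); the dashed line is the 57.2% of all protein-coding genes, and the number of members is in parentheses. Right, median covered length within 10 kb of the transcription start site in kb (points) and the middle 95% of random lists (grey bars); red and blue mark lists above and below other genes at the adjusted threshold, and the Hox genes of groups 1 to 5 lie farthest to the right.

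The breadth of the mark separated lists beyond the presence of a promoter peak. Members of Hox paralog groups 1 to 5 had a median of 15810 bp covered by replicated peaks within 10 kb of the TSS, and groups 6 to 8 had 9849 bp, against 947 bp over all protein-coding genes. Hindbrain regulators had a median of 8859 bp, with 19859 bp at Meis2, 18130 bp at Nr2f1 and 15501 bp at Pax2. The GABAergic lineage had 6532 bp, with 19113 bp at Lhx5, and neural progenitor genes 6081 bp, with 15387 bp at Sox2. The rhombic lip lineage had 5303 bp, with 17820 bp at Zic4, pan-neuronal genes 3866 bp, with 9057 bp at Rbfox3, housekeeping genes 3757 bp, with 10250 bp at Actb, and sonic hedgehog genes 3038 bp, with 7603 bp at Ptch1. These 9 lists lay above other genes in permutation tests against 100000 random lists. The raw permutation p was 2.00e-05, the smallest they can give, for the first 7 of these lists (adjusted permutation p = 5.50e-05). The adjusted permutation p was 2.44e-04 for housekeeping genes and 0.00176 for sonic hedgehog genes. Hox genes lie in clusters and share coverage, so their members are not independent and their permutation p overstates the evidence. Olfactory and vomeronasal receptors lay below, with a median of 0 bp (adjusted permutation p = 5.50e-05), and the other lists did not pass the threshold. For small lists a low median was not testable, since the lower limit of random lists was itself 0 bp, and the sonic hedgehog call ended with a window of 25 kb (adjusted permutation p = 0.0802, range over the alternatives 0.00176 to 0.0802).

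The Hox clusters asked which part of the body axis the tissue came from, since Hox genes are active in order along it. Most anterior genes were marked and most posterior genes were not. Neighbouring Hox genes can share a peak, as Hoxb3 to Hoxb6 did, so they are not independent. The p-values of this paragraph count them as independent and overstate the evidence. Of 15 genes of paralog groups 1 to 5, 13 had a replicated promoter peak, against 1 of 16 genes of groups 9 to 13 (two-sided Fisher's exact p = 6.84e-06, with the same counts in each replicate list). The exceptions were Hoxb1 and Hoxd1 in the anterior groups, which had none, and Hoxb9 in the posterior groups, with a fold of 6.44 (7.13 in replicate 1 and 6.89 in replicate 2). In groups 6 to 8, 7 of 8 genes were marked and Hoxc8 was not (exact adjusted p = 0.186 against all other genes). Against all other protein-coding genes, groups 1 to 5 lay above (exact adjusted p = 0.0484) and groups 9 to 13 below (exact adjusted p = 1.05e-04). The call for groups 1 to 5 against all other genes ended with a 2.5-kb window (exact adjusted p = 0.0534), with the list of replicate 1 (0.0534) and without receptors in the background (0.0906), in a range of 0.0233 to 0.0906.

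Within the clusters, folds were highest at Hoxa2, over the peak from Hoxb3 to Hoxb6, at Hoxc4 and at Hoxd3, and the most posterior gene with a promoter peak was Hoxa7, Hoxb9, Hoxc6 or Hoxd8. In the Hoxa cluster on chromosome 6, Hoxa2 had a fold of 57.6 (53.7 in replicate 1 and 46.2 in replicate 2), Hoxa3 and Hoxa4 shared a 17054-bp peak with 38.6 (38.9 and 14.7 at Hoxa3, 32.6 and 32.3 at Hoxa4), Hoxa1 had 25.1, Hoxa5 and Hoxa6 shared a peak with 22.4, Hoxa7 had 4.46, and Hoxa9, Hoxa10, Hoxa11 and Hoxa13 had none. In the Hoxb cluster, 1 peak of 56097 bp (chromosome 11, 96291511 to 96347607) covered Hoxb3, Hoxb4, Hoxb5 and Hoxb6 with a fold of 49.0, the widest peak of the list. Replicate 1 had 41.7 at all 4 genes, while replicate 2 had 45.6 at Hoxb3, Hoxb4 and Hoxb5 but 12.6 at Hoxb6. Hoxb2 had 46.9, Hoxb7 and Hoxb8 shared a peak with 22.8, and Hoxb13 had none. In the Hoxc cluster on chromosome 15, Hoxc4 had 29.9, Hoxc5 had 24.9 and Hoxc6 had 9.41, and none was found from Hoxc8 to Hoxc13. In the Hoxd cluster on chromosome 2, Hoxd3 had 38.5, Hoxd4 had 28.2 (28.5 and 18.6) and Hoxd8 had 4.62 (4.93 and 3.13), and none was found at promoters from Hoxd9 to Hoxd13. Hoxc5 and Hoxc6 had a covered length of 0 bp because it was counted around their most upstream TSS, while their promoter peaks lay at later ones.

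**Figure D3:**
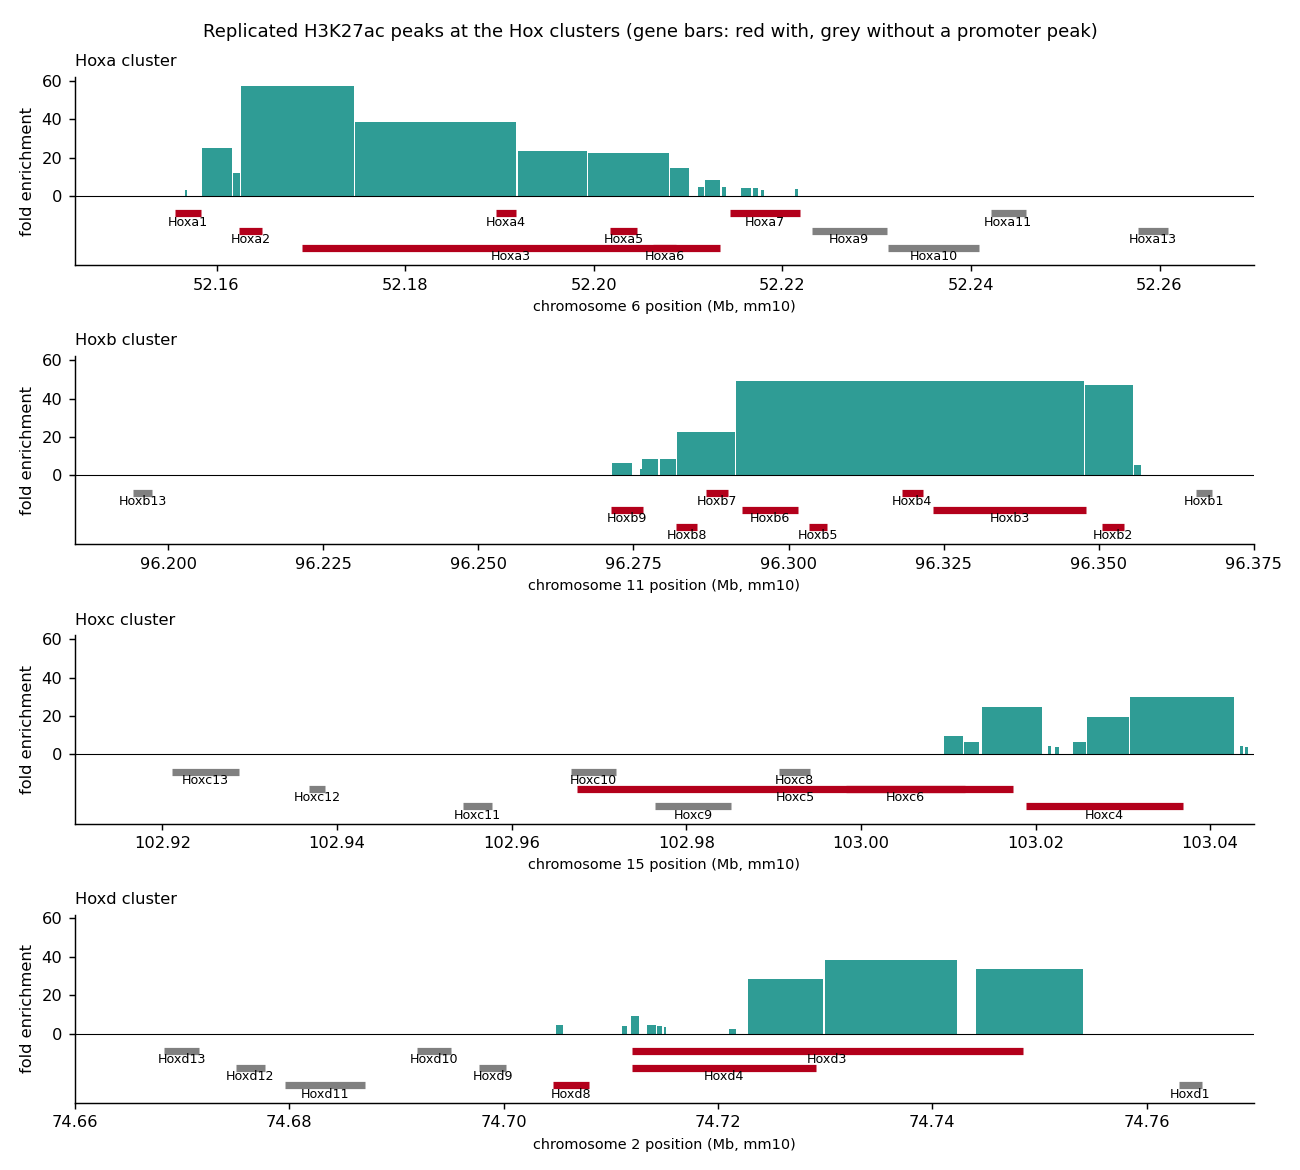
Replicated H3K27ac peaks over the Hoxa, Hoxb, Hoxc and Hoxd clusters: boxes span each peak (horizontal axis, mm10 position in Mb) and rise to its fold enrichment (vertical axis). Bars below are the Hox genes, red with and grey without a replicated promoter peak; the tallest box, at 57.6, lies over Hoxa2, and Hoxb1, Hoxd1, Hoxc8 and the genes of groups 9 to 13 other than Hoxb9 are grey.

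Distal peaks asked where candidate enhancers lay. Of the replicated peaks, 49463 (65.5%, exact binomial 95% interval 65.2 to 65.8) lay more than 2.5 kb from every annotated TSS, with a median fold of 3.92 against 5.95 for the other peaks. The 10 strongest were all found in both replicates. The strongest lay 53693 bp from the TSS of Cstad (chromosome 2, 30655848 to 30663234) with a fold of 63.1 (51.4 in replicate 1 and 53.2 in replicate 2), and another near Cstad (chromosome 2, 30644670 to 30648825) had 55.3. A peak 76396 bp from the chromatin remodeller gene Chd2 (chromosome 7, 73616028 to 73619779) had 62.1, and one 50183 bp from Tob1 (chromosome 11, 94158366 to 94162553) had 53.0. Peaks nearest to Acot11 (52.4), Zfp869 (50.04), Irf2bpl (48.7), Snx10 (47.0) and Psmg4 (46.1) lay outside protein-coding genes. Another, with a fold of 48.5, lay in an intron of Zmiz1, a transcriptional coregulator. The nearest gene names a position and not a target.

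Neighbouring peaks were merged across short gaps to find the longest acetylated regions. The longest region, at Msi2, an RNA-binding protein gene related to Msi1, had 303646 bp covered by 217 peaks (chromosome 11, 88232761 to 88729481) and also held the TSS of Ccdc182. It was followed by the regions of Gse1 and Gins2 (171497 bp), of Zmiz1 (135382 bp), of Cstad, Prrx2, Ntmt1, Asb6 and 1700001O22Rik (115991 bp), of Cacna2d2 and 16 neighbours (106561 bp), of Rere (103831 bp), of Srgap3 and Thumpd3 (99800 bp), of Rbfox3 (97027 bp), of Fyn (95861 bp) and of Ebf3, a transcription factor of neuronal differentiation (92213 bp). Celf4 ranked 13 with 85198 bp, and the Hoxb region from Hoxb2 to Hoxb9 ranked 14 with 82919 bp. Ranks 15 to 20 were those of Ttc28, Mvb12b, Irf2bpl, Myo18a, Rai1 and Arid1b, and ranks 11 and 12 those of Trp53i11 and Ncor2. There were 27348 regions, of which 13372 held a single peak, and the 100 longest held 8.71% of the covered bases. Among those 100, 11 of 15 genes of Hox groups 1 to 5 and 6 of 8 of groups 6 to 8 had a TSS, with Hoxb9, Meis1, Meis2, Nr2f2, Rara, Zic1, Zic4, Lhx5, Lmx1b, Nfix, Notch1, Celf4, Rbfox3 and Sufu, and no other member of the gene lists did. With a merging distance of 5 kb, or with distal peaks only, 12 of the 20 longest regions were still among the 20 longest.

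Motif content asked which of 14 transcription factor sites were frequent in distal peaks. The RFX site, bound by factors that include the progenitor gene Rfx4, had the highest ratio: 90 of 46413 peak windows held it against 9 of as many control windows matched on GC content and chromosome (ratio 10, 95% bootstrap interval 5.76 to 25.3). The MEF2 site had a ratio of 2.18 (1.91 to 2.53), the homeodomain core TAATTA 1.71 (1.62 to 1.80), the HOX-PBX site 1.4997 (1.40 to 1.61) and the POU octamer 1.44 (1.33 to 1.54). The E-box CAGCTG, bound by Ascl1 and Ptf1a, had 1.39 (1.36 to 1.42), the SOX site 1.29 (1.26 to 1.31), and the E-box CAGATG 1.06 (1.04 to 1.08). The NFI site had 1.85 (1.16 to 3.50) from 37 windows against 20, but its interval reached 1 when control windows were drawn again (ratio 1.46) or with only peaks found in both replicate lists (1.44). The CTCF site (1.24, 0.994 to 1.60), GATA (1.02), HNF4 (0.966), ETS (0.897) and a part of the NRSF site (0.917) had intervals that held 1. Without matching on GC content the homeodomain, HOX-PBX and POU ratios fell below 1 (0.8003, 0.823 and 0.827), GATA likewise (0.821), MEF2 came to 1.01, CTCF (1.97), ETS (1.84) and the NRSF part (1.44) rose above 1, and RFX (19) and CAGCTG (2.15) rose further. RFX had 16.8 with only peaks found in both replicate lists, where the whole interval of HNF4 lay below 1 (ratio 0.767). That of CTCF lay below 1 with whole peaks (0.797). GATA had 1.05 (1.01 to 1.09) with a stricter peak threshold. Control windows without matching had a mean GC content of 41.3% against 48.7% in the peaks. In every setting control windows could lie in repeats, so the ratios can also reflect a difference in repeat content, which was not tested.

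**Figure D4:**
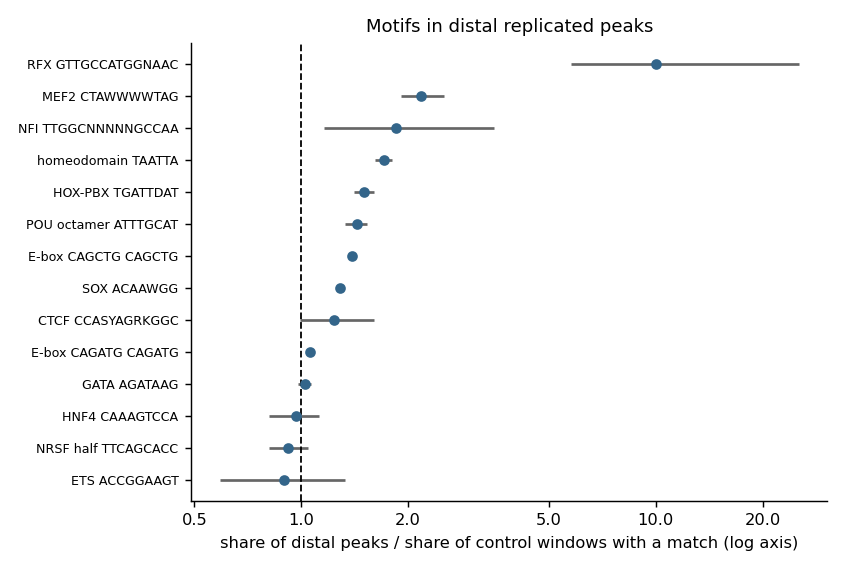
Ratio of the percentage of distal replicated peaks to that of control windows with at least 1 match to each consensus (horizontal axis, log scale; points, with lines for 95% bootstrap intervals over chromosomes). The dashed line marks a ratio of 1; RFX stands at 10 and the intervals of CTCF, GATA, HNF4, ETS and the NRSF part cross the line.

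The density of peaks was compared between chromosomes because the pools held embryos of both sexes. The X chromosome carried few peaks, with 5.36 replicated peaks per Mb against a median of 29.0 and a range of 21.99 to 48.0 on the autosomes. Chromosome 11 had the highest density per Mb, but its 3.57 peaks per protein-coding gene were the autosomal median. Per protein-coding gene, X had 0.966 peaks against an autosomal median of 3.57 and minimum of 2.29. The share of genes with a promoter peak differed less, with 40.6% on X against an autosomal median of 59.5% and minimum of 47.0%. Among X-linked members of the gene lists other than receptors, Hprt had a promoter fold of 18.3, Dcx, which encodes a microtubule protein of migrating neurons, 16.8, Pgk1 12.2, Syn1 11.2, Zic3 10.9, L1cam 8.75 and Sox3 3.63, while Alas2, Arx, Cldn2, Gata1 and Plp1 had no replicated promoter peak. The Y chromosome had 7 peaks. The X density was the lowest of X and the autosomes in both replicate lists.

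**Figure D5:**
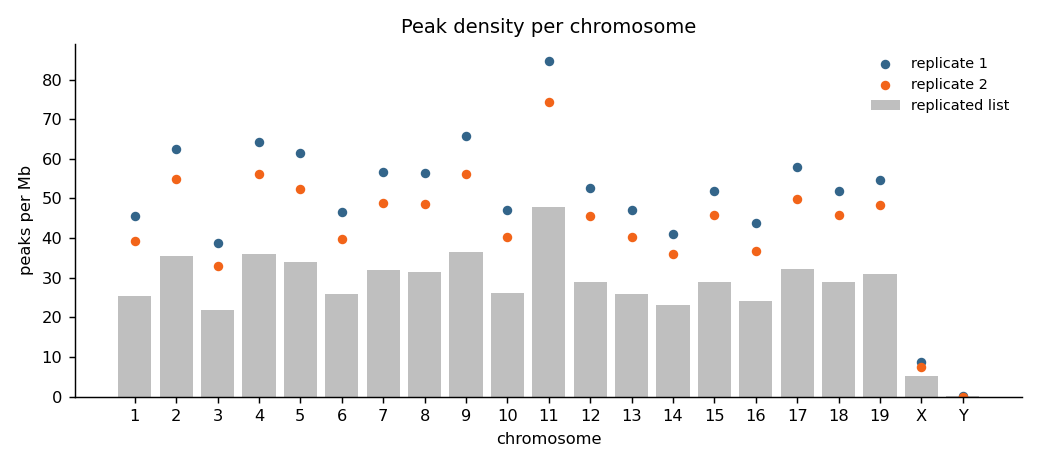
Peaks per Mb (vertical axis) on each chromosome (horizontal axis) for the replicated list (grey bars) and for replicates 1 and 2 (points). The replicated list has between 21.99 and 48.0 peaks per Mb on the autosomes and 5.36 on the X chromosome.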

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

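The peaks outside the assembled chromosomes were used in no comparison, although the replicated list had 9 peaks on 5 unplaced scaffolds, with folds from 2.22 to 53.5. They are given as listed, and whether they hold more than background was not tested.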

How the results depend on the processing

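The restriction to replicated peaks found in both replicate lists and the second draw of control windows were chosen only after the results were seen; the other settings were set in advance. The main results were each recomputed under several settings, which gave 107 comparisons of a result with its value in the report. Of these comparisons, 83 were counted as the same and 24 moved. Shares and the X density ratio had to stay within their error, and counts within 1.5 times. Location ratios and the Hox test had only to keep their direction and their side of the threshold. Of the values for single gene lists and motifs, 343 kept their side of the threshold, 13 newly passed it, 12 no longer did and 3 reversed. Some lists and 5 motifs whose test was not past the threshold in the report changed direction in some settings. Among these lists were the meninges, motor, endothelium and choroid plexus lists. The anterior against posterior Hox difference kept its exact p in 6 of 7 settings and had 8.55e-07 in the pooled list; promoter lists above other genes numbered 6 to 9 against 8, and below 6 to 8 against 7, and promoters stood 2.40 to 6.33 times above shifted lists. For the values that moved, the change follows from the setting's own rule or the cause was not tested. The shared part of replicate 1 was 52.6% with 1 bp of overlap, 31.5% with 50% of both peaks, 48.8% with stricter peaks and 51.2% with equal numbers of top peaks; that of replicate 2 was 65.9%, 36.4%, 61.5% and 56.6%. With stricter peaks 56.2% of pooled peaks were replicated. The distal share was 72.6% beyond 1 kb, 43.8% beyond 10 kb, 62.6% of peaks in both lists, and 68.5% to 70.3% with either replicate left out. Of the 20 longest regions, 12 stayed among the 20 longest with 5-kb merging and 12 with distal peaks only. Among genes with a promoter peak, 2 lists had lower breadth than other genes, cell cycle and choroid plexus, against 1 before. Motifs whose whole interval lay below 1 numbered 1 with whole peaks, 4 without GC matching and 1 with peaks in both lists, against 0. Without GC matching, whose controls were poorer in GC, the POU octamer (0.827), homeodomain (0.8003) and HOX-PBX (0.823) ratios reversed. The X to autosome ratio of density, 0.185, was 0.153 in the pooled list, 0.204 with peaks in both lists, and 0.165 to 0.167 with either replicate left out. No paired analysis was possible because the design has a single group. Depth is unknown, so a missing weak peak cannot be told from a missed one.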

Other observations

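The tests of gene density and of a shared factor on X, the test of replicate-specific markers and the microRNA test were chosen only after the result was seen; the tests of repeats, of a factor of at most 2 and of gene families were set down before theirs. The membership of the family set and the criterion of the marker test were also adjusted after their results were seen, which turned the verdict of the marker test to undecided, and the microRNA test was then limited to copies outside the widest peaks.

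Sorted by family of symbols, broad acetylation gathered at a few gene families. The Hoxa and Hoxb genes and Sox1, Sox2, Sox9 and Sox18 are also members of the gene lists, so the families partly count the same genes again. Of 270 families of symbols with 10 or more members, 6 were enriched among the 5% of genes with most covered bases, at least 5244 bp, in the replicated list and in both replicate lists (one-sided Fisher's exact tests, Benjamini-Hochberg adjustment). The Sox family of developmental regulators had 9 of 19 members there (exact adjusted p = 9.98e-06), namely Sox1, Sox2, Sox4, Sox8, Sox9, Sox11, Sox12, Sox14 and Sox18, with 7 in each replicate list, where Sox14 and Sox18 fell short. Sox18 had no replicated promoter peak, so the 5778 bp covered within 10 kb of its TSS lay in neighbouring sequence. The Pou family had 6 of 16 (exact adjusted p = 0.00360), with Pou3f2, Pou3f3 and Pou3f4, regulators of neuronal differentiation, and Pou4f1 and Pou4f2 of sensory and brainstem neurons; Pou4f2 fell short in replicate 2, with 5 of 16 (0.0383). The Arid family of chromatin proteins had 5 of 10 (exact adjusted p = 0.00341), among them Arid1a, Arid1b and Arid2 of the SWI/SNF complexes; Arid1b fell short in replicate 1, with 4 of 10 (0.0461). The Hoxb family had 8 of 10 (exact adjusted p = 2.12e-07), the Hoxa family 6 of 11 (3.87e-04) and the histone genes 35 of 67 (1.34e-25), but these genes lie in clusters and share coverage, so their members are not independent. Of 11 families of transcription factors tested, 4 passed in all 3 lists, or 2, Sox and Pou, without Hoxa and Hoxb, which joined the set after the count was seen, in line with the hypothesis that broad acetylation in this tissue may gather at such families. All genes here were named after their values were seen.

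Some of the widest peaks lay at microRNA genes. The replicated list had a 35496-bp peak at Mir9-1 (chromosome 3, 88199187 to 88234682), a 33061-bp peak at Mir9-3 (chromosome 7, 79496182 to 79529242) and a 12496-bp peak at Mir124a-1 (chromosome 14, 64584147 to 64596642), genes of microRNAs known for neural differentiation; the first 2 are the widest peaks after that of Hoxb3 to Hoxb6. The 3 copies outside the 20 widest peaks were tested: Mir9-2 had 17234 bp covered within 10 kb, Mir124a-2 16142 bp and Mir124a-3 10923 bp. Their median lay above that of 99.99% of 10000 random sets of 3 other microRNA genes, whose median was 0 bp. Copies of Mir9 and Mir124a may thus lie in broad acetylation, a hypothesis found and tested on the same lists, with 16722 bp, 15531 bp and 10048 bp in replicate 2. Because the other microRNA genes had a median of 0 bp, the test cannot tell these copies from any other microRNA genes near peaks. It covers no other neural microRNA.

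The X chromosome had fewer peaks per Mb than any autosome. Fewer genes on X do not account for it, since X had 0.966 peaks per gene against at least 2.29 on each autosome, and neither do masked repeats, since X had 10.5 peaks per Mb of unmasked sequence against at least 35.0. A lower signal on X by a common factor of at most 2, as from copy number or dosage in embryos of both sexes, stays open. Fold is a ratio over control signal, which a lower copy number also lowers, so copy number alone need not lower the fold. X had 0.562 peaks of fold 5 or more per gene, inside the range of 0.380 to 0.715 for autosomal peaks of fold 10 or more. Of 11 factors from 1 to 2, 0 fitted both of 2 measures. The median fold at marked X promoters needed a factor of 1.2 to 1.3. The number of X peaks per gene of fold 5 or more needed 1.5 to 2. This cannot decide against 1 shared factor, because the median was taken over marked promoters only. X promoters too weak to be called were missing from it, and 40.6% of X genes were marked against an autosomal median of 59.5%. X had 0.531 promoter peaks per gene against at least 0.704 and 0.436 other peaks per gene against at least 1.58. Peaks outside promoters were weaker, with a median fold of 3.86 in introns against 7.96 in promoters. A shared lower signal could thus also remove more of them. Whether that, fewer regulatory elements, sex or calling lowers the other peaks more was not tested.

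Of the 5 lists fixed in advance for other cell types that the dissected tissue could hold, 4 had more genes marked in replicate 1 alone than in replicate 2 alone, while that of microglia ran the other way, with 1 against 3 genes. Of 20 such genes of the choroid plexus, endothelium, mesenchyme, erythroid and microglia lists with a promoter peak in 1 replicate list only, 16 were in replicate 1, among them the choroid plexus genes Aqp1, Clic6, Folr1, Msx1 and Ttr, the endothelial genes Cdh5, Flt1 and Sox18 and the erythroid genes Klf1, Nfe2 and Slc4a1, and 4 in replicate 2, namely Col1a1, Aif1, Irf8 and P2ry12. The longer peak list of replicate 1 could account for this, since other genes were also more often in replicate 1 alone (765 against 348; odds ratio 1.82, 95% interval 0.581 to 7.53, Fisher's exact p = 0.338). A larger share of these cells in the tissue of replicate 1 cannot be told apart from the longer list, because so few genes differ. No biological explanation was tested, since both replicates belong to 1 group.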
